A study of Mus musculus with 4 samples.

How the data were processed

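RNA-seq was performed on 4 cultures of Myc-CaP cells, a prostate cancer line from the Hi-Myc transgenic mouse on the FVB background. The cells stably carried short hairpin RNAs against focal adhesion kinase (FAK, gene Ptk2), called shFAK here, or a negative control hairpin, called shNC. Each line received 10 µM norepinephrine or vehicle for 24 h. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a NEBNext Ultra kit, which does not mark strand. Each of the 4 groups had 1 library, so no difference has a replicate check.

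The authors deposited 1 table of raw read counts per gene for 52636 genes, with gene coordinates, length and biotype. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mm10 build were used. The annotation release, the strand setting and the treatment of multi-mapping reads were not given in the sources used here, so the deposited counts of near-identical copies, overlapping genes and antisense genes are uncertain. The coordinates in the deposited table were identical to GENCODE M21 for 95.2% of the identifiers found in that release. Columns were assigned to samples by their titles, and no per-sample column was left unused. Total counts were 29948640 for shNC vehicle, 27598343 for shNC norepinephrine, 26016936 for shFAK vehicle and 23410486 for shFAK norepinephrine.

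From the deposited counts, effective library sizes were computed with the TMM method of edgeR 4.0.16 in R 4.3.3. Genes with a library-size-scaled count (CPM) of at least 1 in at least 1 of the 4 libraries were kept, which left 12351 genes, 10818 of them protein-coding. For each pair of libraries, a log2 ratio of CPM with a prior count of 2 was given with the exact 99% Clopper-Pearson interval of the counts. A gene met the size rule when its log2 ratio was at least 1 in size and the interval left out 0. The intervals cover counting error only, not variation between cultures, and PCR reads without molecular identifiers are not independent molecules. The difference of the norepinephrine responses used a 99% interval from the normal approximation on the log scale.

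An additive model of hairpin and treatment was fitted to all 4 libraries with the quasi-likelihood test of edgeR, with Benjamini-Hochberg adjusted p under 0.05. It has 1 residual degree of freedom. Its spread is the departure of the libraries from additivity, pooled over genes of like expression. In the main fit a gene's own departure had almost no weight. Dynlt1c, with norepinephrine log2 ratios of 1.34 in shNC and -0.42 in shFAK, still had an SE of 0.14. The p-values hold only if the response to norepinephrine is the same in both lines. They do not measure variation between cultures or between independently made lines. The norepinephrine ratios of the 2 lines share no library, nor do the hairpin ratios of the 2 treatments, so each of these sets of ratios was also compared across genes.

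Before the data were examined, 34 gene lists, the tests, the alternatives and the rule for named genes were fixed. For each list the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 10 bins, as a description of these libraries. Named genes were Ptk2, Ptk2b and the adrenergic receptors; up to 4 members of each described list with the largest mean log2 ratio and a mean CPM of at least 1; up to 12 protein-coding genes per direction with a mean CPM of at least 5 that met the size rule in both hairpin pairs or in both norepinephrine pairs; and up to 6 per direction for norepinephrine in shNC alone and for the difference of responses. Symbols of predicted genes were passed over. Some genes that the rule names and some of the lists are not reported here.

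The alternatives were library size alone, DESeq2 1.42.0 size factors, upper-quartile factors, no filter or a CPM of at least 5, prior counts of 0.5 and 10, a 1.5-fold threshold, protein-coding genes alone, omission of mitochondrially encoded genes, a DESeq2 Wald test, robust empirical Bayes and a 1.2-fold test threshold. After the data had been seen, 3 more were added, and the settings planned for the pairwise counts were extended to the correlations and the size of the response. The added ones took off a spline trend of each library with gene length and transcript GC content, left out genes with a near-identical copy, or required a mean CPM of at least 5. A copy was another annotated gene with at least 95% identity over at least 100 matching bases, found with minimap2 2.31 on GENCODE M21 transcripts. A GC value was available for 99.9% of the kept genes.

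The computations were tested on simulated data made from the means and totals of the real libraries. The 200 changed genes were drawn from those with an expected count of at least 100. Noise was Poisson for the pairs, and for the additive model its spread was close to that of the main fit. No length or GC trend and no departure from additivity were simulated. The counts below check the computation and are not error rates for the real genes, many of which have fewer counts. The size rule recovered 100 of 100 genes changed 3-fold in the simulation of each pair, over 12351 genes, with 5 to 7 unchanged genes past the rule per simulated comparison. The additive model recovered 100 of 100 genes changed 2-fold in the simulated norepinephrine effect and called 3 unchanged genes; in the simulated shFAK effect it recovered 100 of 100 and called 12. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.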

Results

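Gene expression was measured by RNA-seq in Myc-CaP mouse prostate cancer cells carrying a FAK hairpin (shFAK) or a control hairpin (shNC), after 24 h in 10 µM norepinephrine or vehicle. Each of the 4 groups was a single library of 23410486 to 29948640 counts. The series asked how norepinephrine and FAK knockdown affect expression. With 1 library per group, the ratios below compare these libraries, and the intervals given are 99% counting intervals.

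The targeted gene was lower in both shFAK libraries. Ptk2 (ENSMUSG00000022607, mm10 chromosome 15, 73205105 to 73423191) had 3547 counts in shNC vehicle, 3158 in shNC norepinephrine, 1294 in shFAK vehicle and 1248 in shFAK norepinephrine. Its level in shFAK was 40.8% of shNC in vehicle (interval 37.4% to 44.3%) and 43.9% in norepinephrine (40.2% to 47.8%). Its paralog Ptk2b, the kinase PYK2, was at 5.74 CPM in shNC vehicle and 8.89 CPM in shFAK vehicle, log2 ratios of 0.63 in vehicle and 0.67 in norepinephrine. Norepinephrine left Ptk2 at log2 ratios of -0.02 in shNC and 0.09 in shFAK.

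Of the receptors for norepinephrine reported here, Adra1b had 291, 285, 383 and 369 counts in shNC vehicle, shNC norepinephrine, shFAK vehicle and shFAK norepinephrine. Adra2a had 30 to 35 counts per library. Adra1a, Adra1d, Adra2b, Adrb1 and Adrb3 had at most 7 counts in any library. Adra2c had 23 counts in the shFAK norepinephrine library and at most 1 in the other libraries. It was among 119 genes with at least 8 counts in that library and at most 2 in each other library. The other libraries had 4 to 9 such genes each, so the Adra2c counts cannot be told apart from this excess.

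The hairpin comparison asked what differed between the shFAK and shNC lines. Among protein-coding genes with a mean CPM of at least 5 that met the size rule in both pairs, Folh1 had the highest ratios in shFAK. Folh1 (chromosome 7, 86718977 to 86775943), the mouse counterpart of prostate-specific membrane antigen, was 9.41-fold higher in vehicle (log2 3.23, interval 2.81 to 3.77) and 6.15-fold higher in norepinephrine (log2 2.62, 2.24 to 3.08). Cck, which encodes cholecystokinin, was 6.42-fold and 4.55-fold higher. Ablim1, an actin-binding protein, was 4.71-fold and 4.41-fold higher. The chemokine Cxcl5 was 4.29-fold and 3.41-fold higher, and the cytokine Il33 2.92-fold and 2.65-fold.

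The other genes named in this direction were Igfbp5, Slpi, Fbln2, Abca1, Steap4, Plxnd1 and Kank4, with log2 ratios from 1.38 to 2.01. Igfbp5 binds insulin-like growth factors, Slpi is a secreted protease inhibitor, Fbln2 is a matrix protein and Abca1 exports cholesterol. Kank4 overlaps an annotated antisense gene, and its reads cannot be told from those of that gene without strand. In the other direction, 5 genes met the naming rule. Besides Ptk2, these were Selenom (log2 -1.27 in vehicle, -1.25 in norepinephrine), the keratin Krt4 (-1.16, -1.25), Tigit (-1.14, -1.11) and the matrix Gla protein Mgp (-1.16, -1.04). With the length and GC trend taken off, Tigit no longer met the rule in either pair (-0.83 in norepinephrine), and Mgp was at -0.79 in norepinephrine.

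**Figure D1:**
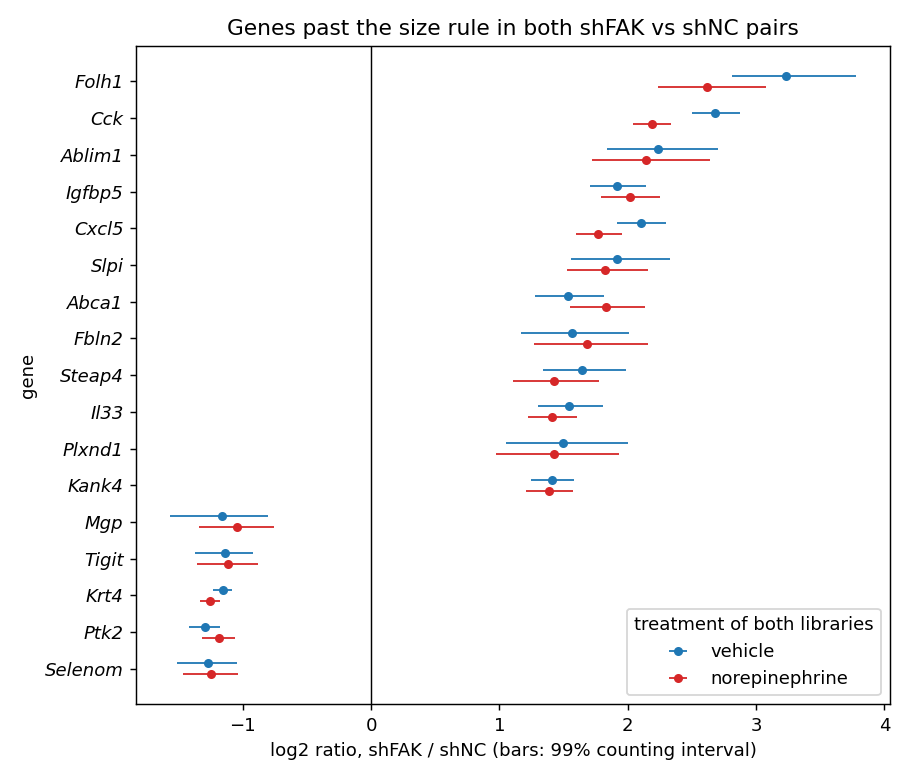
Log2 ratio of shFAK over shNC (x axis) for the genes named in the hairpin comparison (y axis), in vehicle (blue) and norepinephrine (red), 1 library per group, with 99% counting intervals as bars. Folh1 lies farthest to the right, at 3.23 and 2.62, and Ptk2 is at -1.29 and -1.19.

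The size rule was met by 175 genes higher and 57 lower in shFAK under vehicle, and by 323 higher and 78 lower under norepinephrine. The lower count under vehicle was 31 among protein-coding genes, 29 with copied genes left out and 41 with the length and GC trend taken off. Both pairs gave 95 genes higher and 20 lower, against 4.58 and 0.36 for independent lists, and 5 genes went in opposite directions. With the length and GC trend taken off, 41 genes were lower under norepinephrine and 11 in both pairs; among protein-coding genes 28 and 15 were, and with library size only 63 and 13. The log2 ratios of the pairs had a Pearson correlation of 0.60 and a Spearman correlation of 0.70 across 12351 genes, which are not independent replicates; Pearson's r was 0.81 with a mean CPM of at least 5 and 0.11 without a filter. Among the protein-coding genes with a mean CPM of at least 5, 40 were higher and 5 lower in both pairs; 26 and 3 of these met the rule again with the length and GC trend taken off. The shFAK norepinephrine library had counts for 23121 genes, more than the 20442 to 21678 of the others, at the lowest total; the vehicle pair does not use it. In the additive model, edgeR called 2408 genes higher and 2002 lower in shFAK; with the trend taken off the split was 2061 and 2213, with 3139 genes called in the same direction in both. A 1.2-fold test threshold left 1148 genes and the DESeq2 Wald test 1672. The shFAK ratios rose with gene length across genes (Spearman correlation 0.32 in vehicle and 0.47 in norepinephrine). A hairpin effect and any other difference between the 2 lines cannot be separated here.

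Extracellular matrix genes were higher in shFAK as a group. Of 24 measured members, 15 were higher and 3 lower in the additive model over all genes, and 15 and 5 adjusted over the list alone. The median log2 ratio was 0.36 in vehicle and 0.37 in norepinephrine, above all of the 10000 matched random lists in each. Col12a1 was at 1.03 and 1.42, Plau, the urokinase gene, at 0.80 and 1.34, and Col5a1 at 0.82 and 1.11, while Mmp10 was at -0.97 and -0.99. Among mesenchymal genes, 7 of 11 were higher and 1 lower, the same adjusted over the list alone, with medians of 0.42 and 0.40. The mesenchymal list shares Fn1, Col5a1 and Col1a1 with the matrix list, so the 2 lists are not independent. Fn1, fibronectin, was at 0.43 and 0.80 and Zeb2 at 0.42 and 0.64, while Twist2 was at -0.64 and -0.59. Of 3 measured fibroblast markers, 2 were higher and none lower, the same adjusted over the list alone. Their medians were 0.49 and 0.74, at the 90.0 and 91.2 percentiles. Only Pdgfra of these markers had a mean CPM of at least 1, so the calls and medians rest partly on low counts. The fibroblast list shares Col1a1 with the matrix and mesenchymal lists. Mitochondrially encoded genes, a list kept for library quality, took 1.15% to 1.42% of counts. Their median was 0.29 in vehicle, above all of the matched random lists as for matrix genes, and 0.17 in norepinephrine at the 97.2 percentile; 5 of 15 were higher and 2 lower, the same adjusted over the list alone, and 9 and 1 with the trend taken off. Focal adhesion and integrin genes gave 14 of 31 higher and 2 lower (14 and 3 adjusted over the list alone), with medians of 0.15 and 0.21. With the trend taken off, 10 were higher and 5 lower, with medians of 0.10 and 0.09. The integrin Itgb3 was at 1.35 and 1.52 and its partner Itgav at 0.60 and 0.69, while Itga3 was at -0.45 and -0.42.

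Among epithelial genes, 3 of 14 were higher and 3 lower, the same adjusted over the list alone. Their medians were -0.18 in vehicle and -0.14 in norepinephrine, at the 1.56 and 8.71 percentiles. With the trend taken off, the percentiles were 11.93 and 15.68. Krt8 was at -1.42 and -1.59 and shares sequence with another annotated gene, so its counts are uncertain. Krt7 was at -0.47 and -0.78, while Spint1 was at 0.17 and 0.99. Jup, named for the norepinephrine comparison, was at 0.31 and 0.28.

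Interferon-stimulated genes gave 10 of 15 higher and 1 lower, the same adjusted over the list alone, with medians of 0.36 and 0.45 at the 99.8 and 99.5 percentiles. Parp14 was at 1.17 and 1.01 and Stat2 at 0.94 and 1.09. Psmb8, an immunoproteasome subunit, rested on 7 and 10 counts in the shNC libraries against 67 and 59 in shFAK, and has a near-identical copy. NF-kB and cytokine genes gave 6 of 14 higher and 3 lower, the same adjusted over the list alone. Besides Cxcl5, Saa3 was at 3.55 and 2.88, with 7 and 15 counts in shNC and a near-identical copy. Lcn2 was at 2.19 and 1.26. Cxcl2, with 15 and 25 counts in shNC, was at 1.41 (interval 0.40 to 2.81) and 1.03 (0.16 to 2.09).

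Cholesterol and fatty acid synthesis genes were lower in shFAK: 15 of 26 were lower and none higher over all genes, and 16 lower and 1 higher adjusted over the list alone. Their median was -0.32 in vehicle and -0.22 in norepinephrine, below all of the matched random lists in vehicle and at the 0.55 percentile in norepinephrine. Mvk, mevalonate kinase, was at -0.60 and -0.84 and Mvd at -0.51 and -0.56. Ribosome biogenesis genes gave 14 of 25 lower and none higher (15 lower adjusted over the list alone), with medians of -0.20 and -0.27. Fbl, fibrillarin, was at -0.47 and -0.65 and Srm, spermidine synthase, at -0.36 and -0.57. Of 32 cell cycle genes, 5 were higher and 6 lower, the same adjusted over the list alone, with medians at the 62.1 and 41.6 percentiles. With the trend taken off, 1 was higher and 11 lower. Mcm3 was at -0.53 and -0.48, and the proliferation marker Mki67 at 0.17 and 0.42.

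**Figure D2:**
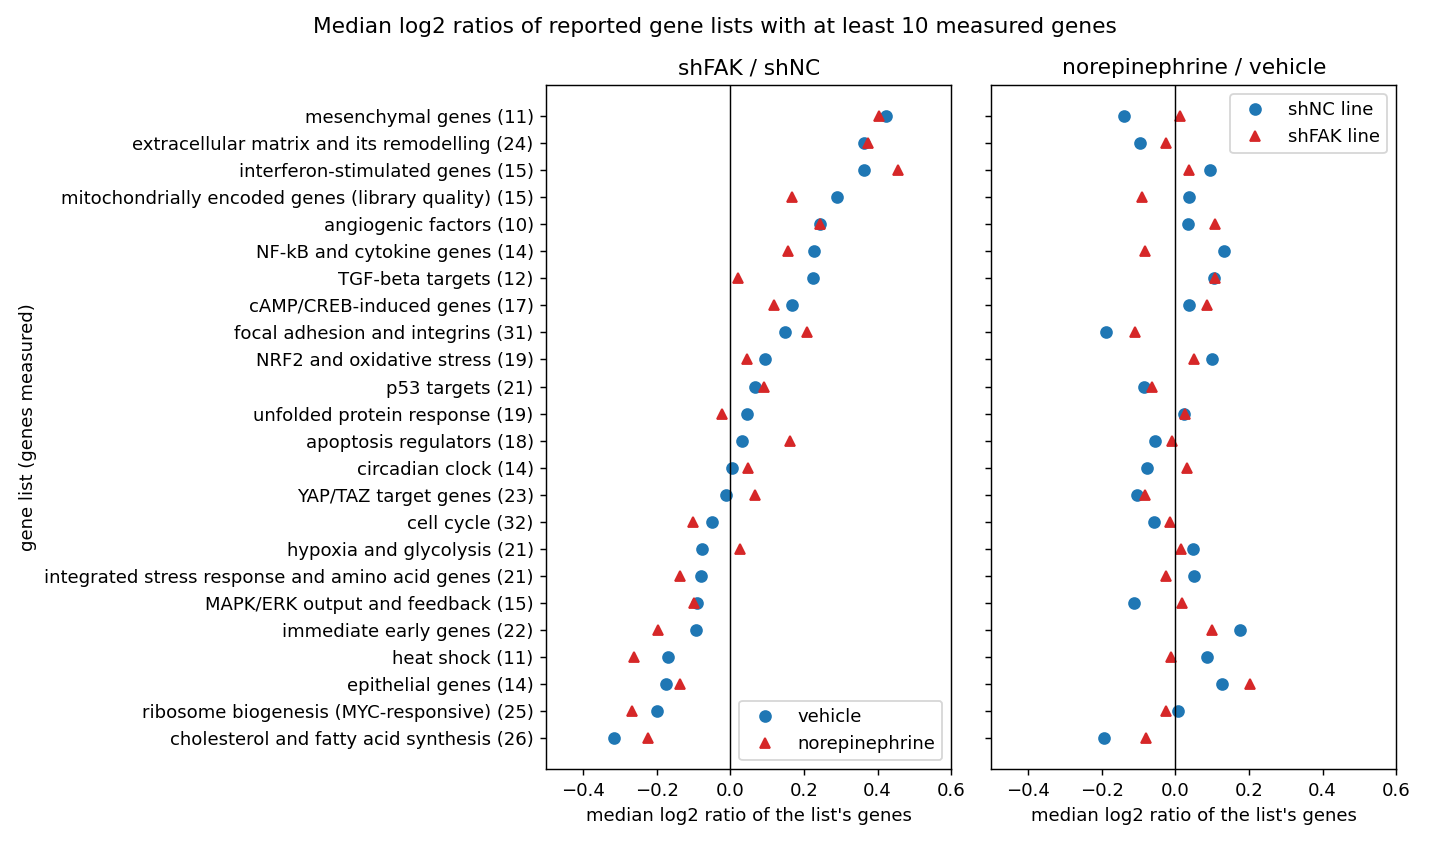
Median log2 ratio (x axis) of the reported gene lists with at least 10 measured genes (y axis, number measured in brackets), for shFAK over shNC (left, by treatment) and norepinephrine over vehicle (right, by line), 1 library per group. Matrix genes lie at 0.36 and 0.37 on the left and cholesterol and fatty acid synthesis genes at -0.32 and -0.22.

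The treatment comparison asked how norepinephrine changed expression in each line. Npy (chromosome 6, 49822710 to 49829507), which encodes neuropeptide Y, was the only gene to meet the naming rule in both lines. It rose from 66 to 213 counts in shNC (log2 1.81, interval 1.32 to 2.40) and from 115 to 289 in shFAK (log2 1.46, 1.06 to 1.90). In the additive model of edgeR its log2 change was 1.63 ± 0.15 (SE), with an adjusted p of 9.66e-23. Both values rest on the spread pooled over genes, not on that of Npy itself. Il33 was at 0.98 in shNC and 0.84 in shFAK, and Mgp at 0.81 and 0.93, short of the size rule but called higher in the additive model (adjusted p of 1.97e-16 and 7.76e-11 by edgeR). Without a filter on low counts edgeR called none of these 3 genes, and DESeq2 gave no adjusted p for them. These 2 genes were named for the hairpin comparison.

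In shNC alone, among protein-coding genes with a mean CPM of at least 5, the largest ratios were those of Hmgn2 (2.10), Npy, Rpl30 (1.67), Sumo2 (1.63), Krt13 (1.37) and Dynlt1c (1.34). Of these, Hmgn2, Rpl30, Sumo2 and Dynlt1c have near-identical copies in the annotation, so their counts are uncertain. The lowest among the same genes were Zfp871 (-1.37), the aminopeptidase Lnpep (-1.34), the copper transporter Atp7a (-1.19), Lcor (-1.15), the kinase Hipk2 (-1.04) and Nr2c2 (-1.04), of which Hipk2 and Nr2c2 share sequence with another annotated gene. In shFAK these 6 genes had log2 ratios of -0.79, -0.48, -0.38, -0.81, -0.53 and -0.15. Ratios fell with gene length across genes (Spearman correlation -0.49 in shNC and -0.29 in shFAK), and of 6 lower genes under the naming rule 2 met it with the length and GC trend taken off.

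The size rule was met by 45 genes higher and 61 lower in shNC, and by 86 higher and 22 lower in shFAK. With the length and GC trend taken off the shNC split was 35 higher and 80 lower, and among protein-coding genes 26 and 23. The shFAK lower count was 6 among protein-coding genes and with a prior count of 10, and 10 with copied genes left out. At a mean CPM of at least 5, 21 genes met the rule in shNC and 11 in shFAK. Both lines gave 5 genes higher and 3 lower, against 0.31 and 0.11 for independent lists, and 2 went in opposite directions. Among protein-coding genes both lines gave 3 higher and 0 lower. Besides Npy these were Vwa5b2 and Kctd19, each at a mean CPM of 1.1, with 11 and 10 counts in shNC vehicle. Across genes the log2 ratios of the lines had a Pearson correlation of 0.27 and a Spearman correlation of 0.49; Pearson's r was 0.59 with a mean CPM of at least 5, 0.56 with a CPM of at least 5 in a library and 0.025 without a filter. The additive model called 623 genes higher and 901 lower with norepinephrine, and 547 and 426 with the trend taken off, with 581 genes called in the same direction in both. That count changed with the filter, the threshold and the test. With a CPM of at least 5 in a library edgeR called 1575, and without a filter 0 (2735 at an unadjusted p under 0.05). Without a filter the pooled spread was weighted as 6.66 degrees of freedom, and in the main fit without a finite limit. A gene's own departure therefore counted for more without a filter. Against a 1.2-fold threshold edgeR called 86, and the DESeq2 Wald test called 87.

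Of 17 measured cAMP/CREB-induced genes, 4 were higher and none lower in the additive model, the same adjusted over the list alone and with the trend taken off. The list median was 0.04 in shNC and 0.09 in shFAK, at the 70.16 and 98.75 percentiles. With the trend taken off, it was at the 51.74 and 62.14 percentiles. Id1 and Id3 also belong to the list of TGF-beta targets. Id3 was at 0.58 in shNC and 0.47 in shFAK, Nr4a2 at 0.66 and 0.23, Id1 at 0.57 and 0.25 and Sik1 at 0.22 and 0.34. Among immediate early genes, 5 of 22 were higher and none lower, the same adjusted over the list alone; with the trend taken off, 1 was higher. Klf2 was at 0.70 and 0.19, Ier2 at 0.51 and 0.29, Egr3 at 0.36 and 1.09 and Egr1 at -0.49 and -0.07; Egr3 and Egr1 were not called.

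Of 31 focal adhesion and integrin genes, 6 were lower with norepinephrine and none higher, the same adjusted over the list alone. The list median was -0.19 in shNC and -0.11 in shFAK, at the 0.04 and 0.02 percentiles. Vcl, vinculin, was at -0.74 and -0.29 and has a near-identical copy, Tns1 was at -0.38 and -0.31, and Itgav at -0.37 and -0.28. With the trend taken off, Itgav was at -0.10 and -0.15 and was no longer called (adjusted p of 0.0046 before and 0.28 after). YAP/TAZ targets gave 6 of 23 lower and none higher, the same adjusted over the list alone, with Myof at -0.46 and -0.28. Extracellular matrix genes gave 4 of 24 lower and 1 higher (5 and 1 adjusted over the list alone), with Lamc1 at -0.62 and -0.31 and Col12a1 at -0.66 and -0.27. Cholesterol and fatty acid synthesis genes gave 4 of 26 lower and none higher (7 lower adjusted over the list alone), with Stard4 at -0.34 and -0.29. With the trend taken off, 5, 4, 7 and 5 genes of these 4 lists were lower, not all of them the same genes.

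**Figure D3:**
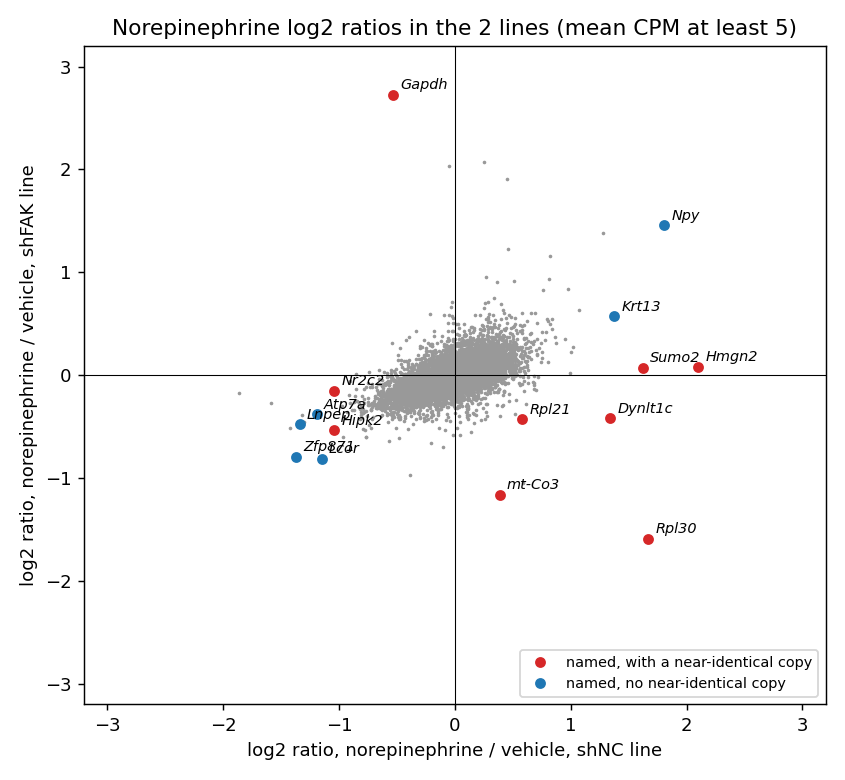
Log2 ratio of norepinephrine over vehicle in the shNC line (x axis) and the shFAK line (y axis), 1 library per group, for 9860 genes with a mean CPM of at least 5 (grey points), with named genes in colour by whether they have a near-identical copy. Npy lies at 1.81 and 1.46, and Gapdh and Rpl30 lie in opposite corners.

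The series also allows the norepinephrine responses of the lines to be set against each other. Among protein-coding genes with a mean CPM of at least 5, the largest difference, shFAK minus shNC, was that of Gapdh, at 3.26 on the log2 scale (interval 3.13 to 3.39), with 9948, 6186, 1328 and 7968 counts in shNC vehicle, shNC norepinephrine, shFAK vehicle and shFAK norepinephrine. In the other direction were Rpl30 (-3.26), Hmgn2 (-2.02), Dynlt1c (-1.76), Sumo2 (-1.55), mt-Co3 (-1.55) and Rpl21 (-1.01). These 7 genes all have near-identical copies, 84 of them for Gapdh, so the values are uncertain. In all, 68 genes met the size rule in the positive direction and 29 in the negative; with a mean CPM of at least 5 these were 6 and 7, and with a CPM of at least 5 in a library 10 and 13.

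The size of the response was read both ways. The 106 genes chosen in shNC had a median log2 ratio, signed by their shNC direction, of 1.32 in shNC and 0.25 in shFAK. The 108 genes chosen in shFAK had 1.42 in shFAK and 0.02 in shNC. With a mean CPM of at least 5 the values in the other line were 0.39 and 0.25, and with a CPM of at least 5 in a library 0.39 and 0.45. A set chosen on 1 pair regresses towards 0 in the other, and no test of the difference was possible with 1 library per group.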

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

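Rpl30 drew attention because its norepinephrine ratio met the size rule in opposite directions in the 2 lines, 1.67 in shNC and -1.59 in shFAK, a difference of -3.26 on the log2 scale. The difference was not tested, since each group had 1 library.

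The tests in the rest of this part were chosen after the results, or some of their members, had been seen. Gapdh, Rpl30, Sumo2 and other genes whose norepinephrine ratios differed between the lines have near-identical copies, and a candidate explanation is that reads were divided differently among copies. Of the 97 genes past the size rule for the difference, 57 had no near-identical copy as defined above, so division among such copies does not apply to them. Reads shared with other sequence, such as overlapping genes, were not tested for these 57. Genes with a copy made up 41.2% of those past the rule and 28.7% of all kept genes. Of the 13 genes past the rule with a mean CPM of at least 5, 11 had a copy. For 37 genes with counted copies, the summed copies moved the opposite way in 62.2% (95% exact interval 44.8% to 77.5%), which does not decide. Copies of the same family, such as Sumo2 and Gm10241, were counted separately, so the genes are not independent as the interval assumes. Sumo2 (-1.55) and its summed copies (1.61) moved apart, while the summed copies of Gapdh (-0.10) and Rpl30 (0.03) moved little and those of Dynlt1c (-0.10) and mt-Co3 (-0.20) moved the same way as the gene. Summed with their copies, Gapdh was at 0.21 and Rpl30 at -0.44, and 3 of the 37 genes met the size rule. Of these, Duxf3 and AW822073 had the same summed value, 4.26. A different response of the lines to norepinephrine stays open and was not tested.

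The norepinephrine ratios of the 2 lines correlated across genes, and both followed gene length and GC content. With that trend taken off, Pearson's r went from 0.27 to 0.17 (95% bootstrap interval over genes 0.13 to 0.21), which argues against the fitted trend as the whole cause. The fall of 0.098 (0.087 to 0.11) is consistent with the trend as part of it. A shared response to norepinephrine and any library effect shared by the 2 norepinephrine libraries stay open, since the labels give no batch. A length or GC effect that the fitted spline does not capture also stays open, and the bootstrap treats genes as independent.

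The shFAK norepinephrine library had counts for the most genes, and 119 genes had at least 8 counts there and at most 2 in each other library, against 4 to 9 genes for the others. Its total, 23410486 counts, was 90.0% of the lowest of the others, which argues against depth. Extra reads per megabase in olfactory and vomeronasal receptor genes were 0.234 times those of other low genes of like GC content (95% bootstrap interval 0.127 to 0.375). The receptor genes still had an excess, 0.524 CPM per megabase against 2.23. The choice of low genes was changed after a first value was seen. Chosen on the other 3 libraries, they gave 0.183 (0.104 to 0.264). The sets were not matched on sequence shared between genes, and the treatment of multi-mapping reads was not given. The ratio therefore does not decide, and genomic DNA stays open. RNA from another source and a response of this culture also stay open and were not tested.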

How the results depend on the processing

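Chosen after seeing the data were the length and GC trend taken off, genes with a near-identical copy left out, a mean CPM of at least 5 and, for the correlations and the size of the response, no filter, protein-coding genes alone, omission of mitochondrial genes, DESeq2 size factors and upper-quartile factors. Leaving out a library gives no test, since the additive model would have no residual degrees of freedom. With 1 library per group, the additive model was the only fit that compared treatments within lines and lines within treatments. Library size alone, DESeq2 size factors, upper-quartile factors, a prior count of 0.5 and omission of mitochondrial genes kept every pairwise count within 1.5 times; the cause of the changes below was not tested. Correlations and medians that moved by less than 0.1 were taken as kept. The intervals cover counting error at the depth sequenced.

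Genes past the size rule, in the order norepinephrine in shNC (106), norepinephrine in shFAK (108), shFAK in vehicle (232), shFAK in norepinephrine (401) and difference of responses (97), numbered 29, 14, 85, 131 and 23 with a CPM of at least 5 in a library, and 21, 11, 68, 107 and 13 with a mean CPM of at least 5. A 1.5-fold threshold gave 460, 210, 653, 1391 and 215. Without a filter, norepinephrine in shNC gave 171, norepinephrine in shFAK 397 and shFAK in norepinephrine 685. A prior count of 10 gave 62, 67 and, for the difference, 39. Protein-coding genes alone gave 49 in shNC and 62 for the difference, and leaving out genes with a copy 64 and 57.

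The additive model called 1524 genes for norepinephrine, 0 without a filter (2735 at an unadjusted p under 0.05), 86 against a 1.2-fold threshold, 87 with DESeq2 and 973 with the trend taken off (547 higher and 426 lower, from 623 and 901; 581 of the 1524 kept in the same direction). For shFAK it called 4410, and 1623, 1148 and 1672 under the first 3 of these; with the trend taken off the split was 2061 higher and 2213 lower, with 3139 of the 4410 kept in the same direction. The correlation of the norepinephrine ratios went from 0.27 to 0.56 with a CPM of at least 5 in a library and 0.59 with a mean CPM of at least 5, and that of the shFAK ratios from 0.60 to 0.79 and 0.81; without a filter they were 0.025 and 0.11. The median response in shFAK of genes chosen in shNC went from 0.25 to 0.39 under both. The median in shNC of genes chosen in shFAK, 0.019, went to 0.45 and 0.25, and turned to -0.067 with a prior count of 10, -0.018 with the trend taken off, -0.080 in protein-coding genes and -0.015 without a filter. Of the ratios of named genes, 416 values moved outside the 95% counting interval and 5636 did not, and none that met the size rule changed sign. Of the list medians, 25 values moved.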

Other observations

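In the additive model, 2408 of all 12351 genes were called higher in shFAK and 2002 lower, and the counts below are to be read against that share. Of 14 circadian clock genes, 2 were higher and 3 lower in shFAK in the additive model, the same adjusted over the list alone. Their medians were at the 40.6 percentile in vehicle and 51.5 in norepinephrine. Tef was at -0.82 in vehicle and -0.81 in norepinephrine, Ciart at -0.80 and -0.72 and Nr1d1 at -0.54 and -0.33. Of 15 MAPK output genes, 3 were higher and 6 lower, the same adjusted over the list alone, with Etv4 at -0.64 and -0.58 and Emp1 at -0.59 and -0.50, while Dusp4 was at 0.48 and 0.56. Of 17 cAMP/CREB-induced genes, 6 were higher and 1 lower, the same adjusted over the list alone; Ppargc1a was at 1.23 and 1.10 and Nr4a1 at -0.84 and -0.83. Of 21 p53 targets, 7 were higher and 2 lower (8 and 3 adjusted over the list alone), with medians at the 82.1 and 75.1 percentiles. Cdkn1a was at 0.72 and 0.38 and Pmaip1 at 0.57 and 0.51. Of 11 heat shock genes, 2 were higher and 6 lower, the same adjusted over the list alone, with Hspe1 at -0.34 and -0.58 and Hspa1a, which has near-identical copies, at 0.36 and 0.58.

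Immediate early genes were called both ways in shFAK: 2 of 22 were higher and 7 lower (2 and 9 adjusted over the list alone). Their medians were -0.09 in vehicle and -0.20 in norepinephrine, at the 6.55 and 1.16 percentiles. With the trend taken off, the percentiles were 13.13 and 10.96. Fos, with 50 to 157 counts per library, was at 1.76 and 1.02. Egr1, with 31 to 79 counts, was at -0.94 and -0.51, and its interval in norepinephrine included 0 (-1.45 to 0.33). Of 12 immune markers 2 were measured, and of 10 endothelial markers 1; none was called higher or lower in shFAK. Cd14 had 447, 508, 372 and 436 counts in shNC vehicle, shNC norepinephrine, shFAK vehicle and shFAK norepinephrine.

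Other lists had members called both ways in shFAK in the additive model, as did all 12351 genes (2408 higher and 2002 lower). Of 23 YAP/TAZ targets, 6 were higher and 5 lower, of 21 hypoxia and glycolysis genes 4 and 5, of 21 integrated stress response genes 1 and 4, of 10 angiogenic factors 4 and 2 and of 12 TGF-beta targets 4 and 2, each the same adjusted over the list alone. Of 18 apoptosis regulators, 6 were higher and 3 lower (6 and 4 adjusted over the list alone), of 19 unfolded protein response genes 5 and 2 (7 and 3), and of 19 NRF2 and oxidative stress genes 5 and 3 (7 and 3), or 9 and 2 with the trend taken off.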
